A study of Mus musculus with 6 samples.

How the data were processed

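The data were RNA-seq profiles of mouse heart from 6 samples in 3 groups of 2: sham surgery, transverse aortic constriction (TAC), and TAC with knockdown of Snai1, each labelled 2 weeks. Per the labels' protocols, total RNA was extracted with TRIzol from heart tissue and cultured cells, with no statement of which sample came from which beyond the tissue label of heart, and libraries were made with a SMARTer mRNA-seq kit. The submitters' processing notes name limma, with no version, and the genome build mm10. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so reads of a gene cannot be told from those of an overlapping antisense gene or a near-identical copy.

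The deposited table held 19320 genes by symbol in 6 columns, as log2 values. From the values themselves, each deposited log2 column equalled log2 of CPM (reads scaled to a total of 1000000) with 0.5 added to the reads and 1 to the library total, the form that the voom function of limma writes. Undoing the log gave totals of 15866094 to 17745141 and values in steps of 0.2 rather than whole reads. Within each group the share of reads held by the first of the 2 columns never left the range from 0.4 to 0.6. Each pair of columns was therefore resolved as 2 mixtures of 2 libraries, with 60% and 40% shares in the first column and 40% and 60% in the second. This gave whole counts, within a tolerance of 0.05, for 99.9% of 115920 values and 0 negative values. Other first shares gave fewer whole counts: 57.3% of values at 55%, 18.8% at 58%, 15.3% at 62%, 22.6% at 65%, 30.9% at 70% and 36.4% at 80%. Negative values numbered 7775 at 55%, 6130 at 58% and 0 at the 4 larger shares, so that the whole counts and not the negative values set 60% apart from these. The same step on the 12 pairs of columns from different groups gave 20.6 to 21.1% and between 4441 and 5511 negative values of 38640 per pair. No source used here records such a mixing step. A resolved library carries the replicate number of the column in which it has the larger share. The resolved totals were 14835962 and 17411291 reads in sham, 18094371 and 17221296 in TAC, and 15254674 and 18247816 with knockdown, so that 3 reads corresponded to between 0.164 and 0.202 CPM. Among genes with a mean of at least 500 reads, the log2 difference between the 2 libraries of a group was 5.05 to 5.11 times as variable after resolving as before. A ratio of about this size follows from the 60% and 40% weights themselves and is no test of the resolving.

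All samples were fitted together with 1 mean per group by limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend, in R 4.3.3) on log2 CPM of the resolved counts, with 0.5 added to the reads and library totals as the only scaling. A fold change is thus on the log2 scale with that addition and understates the change of genes with few reads. Standard errors of fold changes are those of the moderated fit, with 3 residual and 11.3 prior degrees of freedom. Genes were kept when at least 2 libraries reached the CPM that 10 reads make in the median library and all libraries together held at least 15 reads. This left 14447 genes and removed 4873 with 0.0583% of the reads. P-values were adjusted by the Benjamini-Hochberg method in each comparison, and a call needs an adjusted p below 0.05. The plan written before the data were examined, for a file on a log scale, was the same fit on the deposited log2 values with all rows. It was replaced once the columns were found to resolve as mixtures and before any gene was tested. The spread between 2 mixtures of the same libraries is not a spread between samples. The counts of the planned fit stand beside those of the resolved libraries. Count models were not used: neither edgeR nor DESeq2 was run. The plan tied the test to the form of the deposited file, which is on a log scale. The resolved values are whole counts, so such a test would have been possible.

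The procedure was tested on simulated data made from the real means and library totals, mixed and logged in the same way, with 200 genes of at least 20 mean reads changed between TAC and sham and none between knockdown and TAC. Resolving the simulated columns gave whole counts and no negative value. Of the genes changed 2-fold and 4-fold between TAC and sham, limma recovered 77% and 90% of 100 each among 14301 tested, and called 10 of 14101 unchanged genes. The median standard error was 0.16 on the log2 scale in the simulation and 0.19 in the data. On the simulated columns in mixed form the same test called 64.2% of unchanged genes in that comparison. Camera called the 4 changed sets and 0 of 35 unchanged ones. The simulated genes were drawn independently, so this did not test camera on lists whose members vary together. In the data the estimated correlation was, for example, 0.72 in the cardiac stress list and 0.41 in the macrophage list.

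A total of 40 gene lists for heart tissue, pressure load, fibrosis, the mesenchymal transition and the cell types of the heart were written at the same stage. The list of mitochondrially encoded genes had no tested member, and the other 39 were tested with camera (preset correlation of 0.01, with an estimated correlation beside it) and fry (for 1 direction, and for members changing in either), adjusted over the 39 lists of a comparison. Named genes followed a rule also written then: Snai1, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap, filled up with the smallest unadjusted p where fewer passed and said not to pass, and up to 4 members of each list described, those with the smallest unadjusted p. Rows without a gene symbol, predicted gene models and sex-linked genes were not named. Nppb, Myh7, Col1a1, Col3a1, Snai2, Twist1 and Zeb1, and in the closing section Gp5, Sall3, Ednra, Apoe, C3ar1, C4b, Stab1, Pdk4, Ddx3y, Xist, Gm10925 and Myh6, were named outside the rule and chosen after their values were seen. A platelet and a globin list were written after the first results. Coordinates are those of GENCODE M21 (GRCm38, the assembly that mm10 is), in which 14174 of the tested symbols (98.1%) were found.

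Correlations and covariances of the log2 fold changes of comparisons that share libraries, and the share of genes with opposite signs, were set beside 100 draws of unchanged groups with the same spread. Genes were drawn independently of each other, so the SDs of the draws are too small where genes vary together. The alternatives tried were 2 other pseudocounts, no filter, a stricter filter, quantile and median ratio scaling, limma without the trend, robust limma, limma-voom, a fit of 2 groups only, the replicate number as a block, each library left out in turn, a minimum log2 fold change of 1, other tests for lists, and the columns as deposited. Limma-voom, the columns as deposited and the either-direction test of fry were added after the data were seen. With 2 libraries per group a test rests on the spread pooled over the groups, and a group left with 1 library is assumed to vary like the others. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.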

Results

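Messenger RNA of samples labelled as mouse heart was sequenced in 3 groups of 2 samples, all labelled 2 weeks. The groups were wild-type mice after sham surgery, wild-type mice after transverse aortic constriction (TAC), which narrows the aorta and puts a pressure load on the left ventricle, and mice with TAC and knockdown of Snai1. Snai1 encodes Snail, a transcriptional repressor known for driving epithelial and endothelial cells towards a mesenchymal state. The series asks how lowering Snai1 alters gene expression under pressure load. Its title holds an abbreviation that is not explained, and the extraction protocol mentions cultured cells beside heart tissue. The tissue label of every sample is heart, and no source used here settles further which material was sequenced. The libraries held 14835962 and 17411291 reads in sham, 18094371 and 17221296 in TAC and 15254674 and 18247816 with knockdown, and 14447 genes were tested.

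The 2 deposited columns of a group differed by less than the sampling of reads would allow, with a chi-square per gene of 0.519 in sham, 0.58 in TAC and 0.529 with knockdown. Resolving each pair of columns as 60:40 and 40:60 mixtures of 2 libraries gave whole read counts for 99.9% of the 115920 values, within a tolerance of 0.05, and no negative value. In the 12 pairs of columns taken from different groups, the same step gave whole counts for 20.6 to 21.1% of values. The values below come from the resolved libraries, in CPM (reads scaled to a library total of 1000000). In these, over genes with a mean of at least 500 reads (5016 in sham, 5402 in TAC and 5285 with knockdown), the log2 difference between the 2 libraries of a group had an SD of 0.22 in sham, 0.21 in TAC and 0.19 with knockdown, against 0.04 in each pair of deposited columns. The larger SD of the resolved libraries follows from the 60:40 weights and is not a separate observation. Nothing in the labels says that the 2 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

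**Figure D1:**
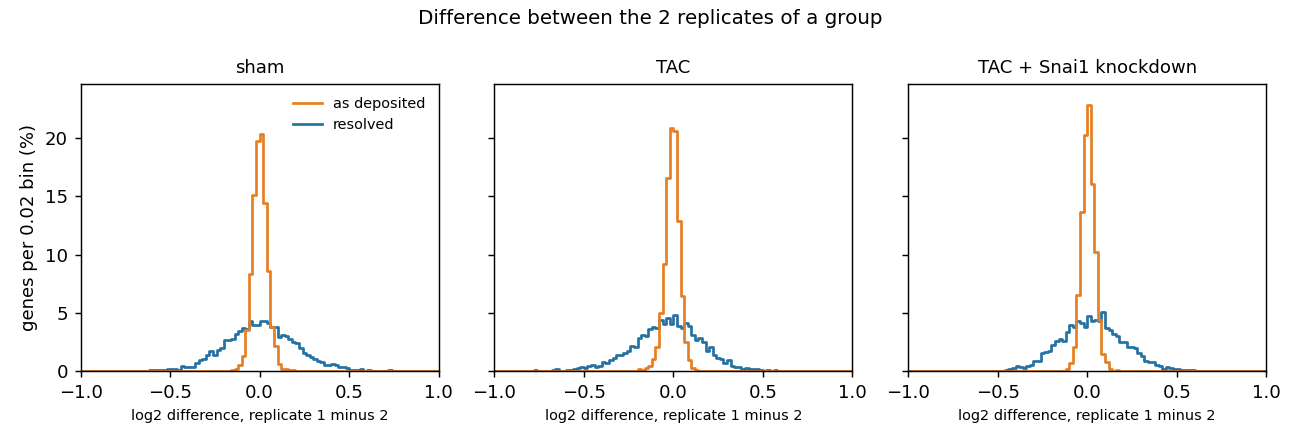
Log2 difference in CPM between replicate 1 and replicate 2 of each group (x axis) against the percent of the 5246 genes with a mean of at least 500 reads that fall in each bin of 0.02 (y axis), for the columns as deposited and for the resolved libraries. The share of genes that differed by more than 0.2 was 0.152% as deposited and 30.7% once resolved in sham, 0.0762% and 29.1% in TAC, and 0.0381% and 27.4% with knockdown. The widening follows from the weights used to resolve the columns.

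Snai1 itself, on chromosome 2 from 167538195 to 167542814 (plus strand, GRCm38), was a low-abundance transcript with between 50 and 81 reads per library. It stood at 5.12 and 3.45 CPM in sham, 4.48 and 4.24 in TAC and 3.41 and 2.74 with knockdown. Both knockdown libraries lay below all 4 others, an ordering in the direction of the label. The knockdown level was 0.704 times that of TAC, a log2 fold change of -0.51 ± 0.33 (SE), which did not pass the test across all genes (limma, Benjamini-Hochberg adjusted p = 0.999). TAC and sham differed by 0.05 ± 0.33 on the log2 scale (adjusted p = 0.974), a sign that turned to -0.23 when sham replicate 2 was left out and to -0.02 with quantile normalization. In the columns as deposited the knockdown difference was also -0.51, with an adjusted p of 2.41e-06. Other transcription factors of the same transition showed no called change in any comparison: Snai2 had a log2 fold change of -0.25 between knockdown and TAC, Twist1 of -0.01, Zeb1 of 0.03 and Zeb2 of 0.29.

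**Figure D2:**
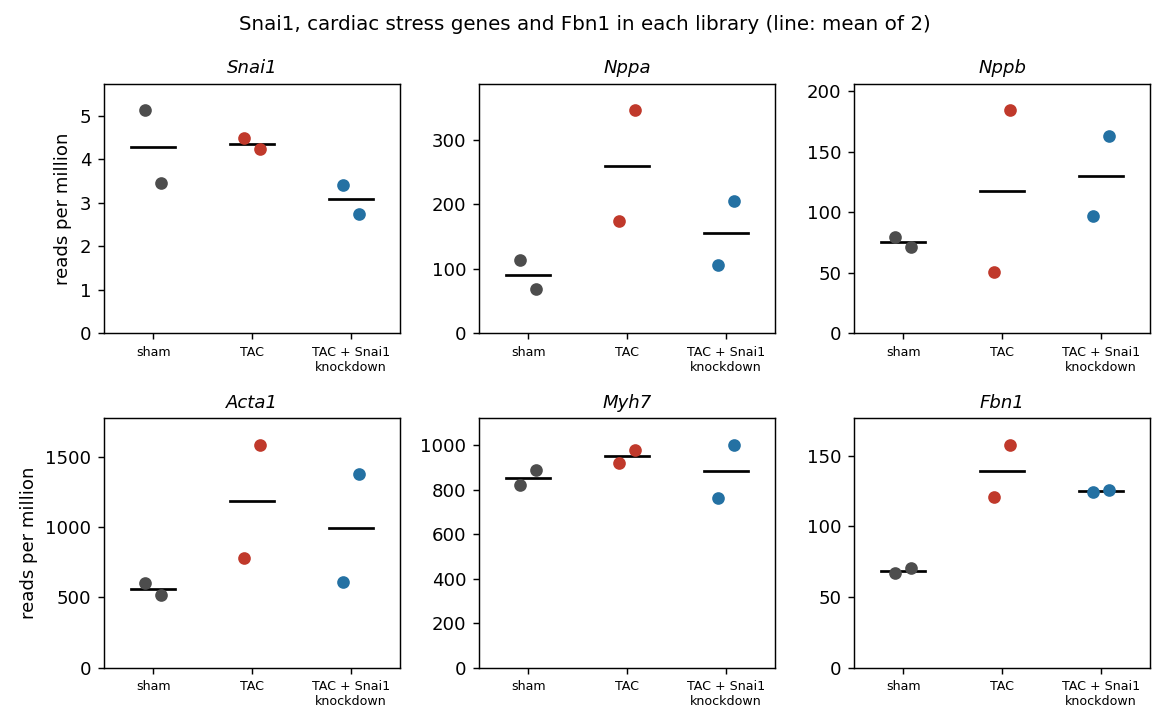
CPM (y axis, from 0) of Snai1, the cardiac stress genes Nppa, Nppb, Acta1 and Myh7, and Fbn1 in each of the 6 libraries. Points are libraries and lines are means of 2. Snai1 ran from 2.74 to 3.41 with knockdown and from 3.45 to 5.12 in the other libraries, and Nppb was 50.8 and 184 in the 2 TAC libraries.

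Between TAC and sham, 12 genes rose and 11 fell. Of the fixed lists, 2 of 29 macrophage markers rose, and 2 of 10 erythroid and platelet markers and 2 of 24 immediate early genes fell. Mpeg1, which encodes the pore-forming protein perforin-2 of macrophages, rose 3.63-fold, from 14.0 ± 1.14 to 50.8 ± 5.86 CPM (mean ± SD, n = 2). Ms4a4a rose 6.46-fold, Clec4n (the fungal receptor dectin-2) 6.43-fold, Lgals3 (galectin-3) 6.05-fold and Ms4a7 5.16-fold. Ccl8, a chemokine that attracts monocytes, rose 14.8-fold from 4 and 2 reads in the sham libraries to 41 and 71 reads. Fbn1, which encodes the microfibril protein fibrillin-1, rose 2.00-fold, from 68.8 ± 2.14 to 139 ± 26.0 CPM.

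Among the genes that fell, Nr4a1 and Nr4a3, orphan nuclear receptors induced within minutes by many stimuli, were 4.75-fold and 4.04-fold lower in TAC, and Nr4a1 went from 80.4 ± 19.1 to 16.7 ± 2.14 CPM. The platelet genes Ppbp (the precursor of several platelet chemokines) and Itga2b (integrin alpha IIb) were 11.3-fold and 6.24-fold lower. Nrgn, which encodes the calmodulin-binding protein neurogranin and is also abundant in platelets, was 7.62-fold lower. Smaller falls were seen in Camk2b (2.17-fold), the planar polarity gene Prickle3 (1.64-fold), the cardiac gene Lrrc10 (1.60-fold), the myosin gene Myh7b (1.59-fold) and the splicing factor gene Sfpq (1.57-fold). Smaller rises were seen in Tmem267 (2.13-fold), the ketone body enzyme gene Bdh1 (1.90-fold) and the cholesterol exporter gene Abca1 (1.89-fold).

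In all, 12 genes were higher and 11 lower in TAC than in sham (limma, Benjamini-Hochberg adjusted p below 0.05, smallest 0.000212 for Nr4a1), and 1383 genes had an unadjusted p below 0.05, where chance gives 722. The groups did not overlap for 40.1% of genes, where chance gives 33.3%. Leaving out 1 library cannot turn the sign of a gene whose groups do not overlap, so a kept sign of such a gene is no test. With median ratio scaling 12 genes were higher and 17 lower, and in the columns as deposited 7638 of 19320 genes were higher and 6174 lower. Without sham replicate 1 the test called 21 genes higher and 24 lower, without sham replicate 2 it called 7 and 8, without TAC replicate 1 it called 27 and 16, without TAC replicate 2 it called 1 and 3, and without knockdown replicate 1 it called 10 and 7. Of the 23 called genes, 2 (Nr4a1 and Nrgn) passed in all 6 fits without 1 library and 5, among them Camk2b, Myh7b and Prickle3, passed in none, and all 23 kept their sign in each.

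**Figure D3:**
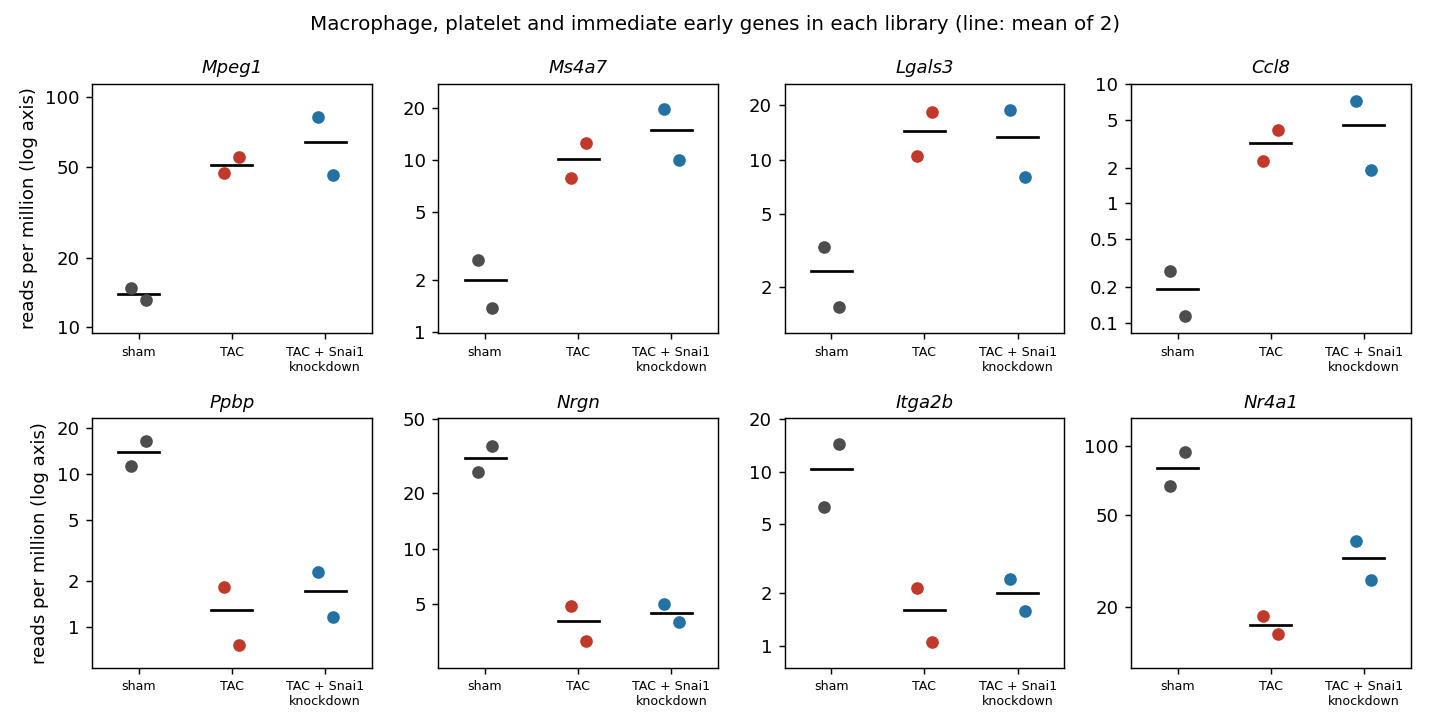
CPM (y axis, log scale) of macrophage genes (Mpeg1, Ms4a7, Lgals3), the chemokine gene Ccl8, platelet-associated genes (Ppbp, Nrgn, Itga2b) and Nr4a1 in each of the 6 libraries. Points are libraries and lines are means of 2. Mpeg1 ranged from 13.2 to 14.8 in sham and from 45.7 to 82.1 in the libraries with TAC, and Nrgn from 25.7 to 35.9 and from 3.19 to 5.05.

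The list of monocyte and macrophage markers was higher as a group in TAC than in sham (camera, adjusted p = 2.45e-05; adjusted p = 0.887 with an estimated correlation). Of its 29 tested members, Ms4a7 and Lgals3 rose, none fell, and 9 rose and 1 fell when adjusted over the list alone. Cd68, a lysosomal protein of macrophages, had a log2 fold change of 1.46 ± 0.28 and the scavenger receptor gene Cd163 one of 0.62 ± 0.17, neither past the test over all genes. The median of the list was 0.33 on the log2 scale, and it lay between 0.26 (without TAC replicate 2) and 0.53 (without TAC replicate 1) when 1 library was left out. Medians of the endothelial list (0.08), the resting fibroblast list (0.10) and the pericyte and smooth muscle list (0.04) were closer to 0. The lymphocyte list was lower (median -1.64, adjusted p = 4.52e-05; adjusted p = 0.755 with an estimated correlation), none of its 12 members passed alone, and without sham replicate 1 its median was -0.32 and it was not called, while without sham replicate 2 it was -2.61. The 4 globin genes, a blood marker, summed to 2498 CPM in sham replicate 1, to 1287 in sham replicate 2 and to between 1098 and 1599 in the other libraries.

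The erythroid and platelet list was lower with a median of -0.67 (camera, adjusted p = 1.07e-11; adjusted p = 0.182 with an estimated correlation). Ppbp and Itga2b fell among its 10 tested members, 7 fell when adjusted over the list alone, and Pf4, another platelet chemokine gene, had a log2 fold change of -0.90 ± 0.23. The immediate early list, titled when written as sensitive to tissue handling, was lower with a median of -0.30 (adjusted p = 1.06e-08; adjusted p = 0.597 with an estimated correlation). Nr4a1 and Nr4a3 fell among its 24 members and 5 fell when adjusted over the list alone. The stress factor gene Atf3 had a log2 fold change of -1.95 ± 0.40 and the matricellular gene Ccn1 one of -0.77 ± 0.16, without passing over all genes. Heat shock genes were lower with a median of -0.31 (adjusted p = 1.06e-08; adjusted p = 0.597 with an estimated correlation). None of the 18 passed over all genes and 8 fell when adjusted over the list alone, with a log2 fold change of -2.29 ± 0.45 for Hspa1b, which shares most of its sequence with Hspa1a, and -0.58 ± 0.12 for Hspa8. The macrophage, erythroid and platelet, immediate early and heat shock lists were called in each of the 6 fits without 1 library. The erythroid and platelet median was -0.29 without sham replicate 1 and -1.06 without sham replicate 2, and the immediate early median was -0.16 without sham replicate 2.

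The cardiac stress and fetal gene list was higher in TAC (median 0.24, camera adjusted p = 0.00603; adjusted p = 0.898 with an estimated correlation), and its members differed widely between the TAC libraries. The atrial list, which shares Nppa with it, had a median of 0.38 and was not called (camera adjusted p = 0.108). Nppa, which encodes atrial natriuretic peptide, had 173 and 346 CPM in TAC against 113 and 68.2 in sham, a log2 fold change of 1.48 ± 0.31 (limma, adjusted p = 0.0703). Acta1, the skeletal muscle actin gene re-expressed in loaded heart muscle, had 782 and 1582 against 601 and 515, and Nppb, the gene of brain natriuretic peptide, 50.8 and 184 against 79.5 and 70.9. Myh7, the slow myosin heavy chain gene, had a log2 fold change of 0.15. None of the 16 members of the cardiac stress list passed over all genes and 4 rose when adjusted over the list alone. Without TAC replicate 2 the median was 0.02 and the list was not called, and without TAC replicate 1 it was 0.56.

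Structural matrix genes were higher (median 0.19, adjusted p = 0.0158; adjusted p = 0.898 with an estimated correlation). Fbn1 alone rose among its 36 members, and when adjusted over the list alone 5 rose and 3 fell, with log2 fold changes of 0.91 ± 0.18 for Mfap5, 0.60 ± 0.12 for Fbln2 and -0.97 ± 0.20 for Thbs1. The fibrillar collagen genes Col1a1 and Col3a1 had log2 fold changes of 0.23 and 0.62, with 243 and 363 CPM in TAC replicate 2 against 143 and 199 in TAC replicate 1. Without TAC replicate 2 the median of the list turned to -0.08, without TAC replicate 1 it was 0.51, and it was not called without TAC replicate 2 or sham replicate 2. Basement membrane genes were higher (median 0.21, adjusted p = 0.0299; adjusted p = 0.766 with an estimated correlation), none of the 19 passing over all genes and 3 rising and 1 falling when adjusted over the list alone, among them Col4a1 at 0.62 ± 0.14 and Col4a2 at 0.60 ± 0.13. The call was lost without sham replicate 1, sham replicate 2 or TAC replicate 2 (median 0.12 without the last). The lists of activated fibroblast markers, of TGF-beta and BMP signalling and of transcription factors of the mesenchymal transition were not called, with adjusted p of 0.482, 0.77 and 0.77 by camera.

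Metabolic lists shifted little. Fatty acid oxidation genes were lower (median -0.13, adjusted p = 0.0299; adjusted p = 0.898 with an estimated correlation) and glycolysis genes higher (median 0.17, adjusted p = 0.0368; adjusted p = 0.597 with an estimated correlation). No gene of either list passed, over all genes or adjusted over the list alone. The fatty acid oxidation median turned to 0.07 without sham replicate 2, the call of that list was also lost without TAC replicate 2 (median -0.03), and the glycolysis call was lost under both scaling alternatives and without any 1 of the sham or TAC libraries. Cell cycle genes were higher (median 0.53, adjusted p = 0.00199; adjusted p = 0.898 with an estimated correlation), with no member of 35 passing in either way, a median of 0.06 and no call without TAC replicate 2, 0.33 and no call without sham replicate 1, and 1.44 without TAC replicate 1. Schwann cell and neural markers were lower (median -0.48, adjusted p = 0.0368; adjusted p = 0.597 with an estimated correlation), with no member of 11 passing in either way, and the call was lost under both scalings and without sham replicate 1, sham replicate 2 (median -0.79) or TAC replicate 2. Of the 39 lists tested, these 6 higher and 6 lower ones were called in this comparison, 0 held with an estimated correlation, and fry called 0 in its test for 1 direction (smallest adjusted p = 0.119). Its test for members that change in either direction called 3: erythroid and platelet markers (adjusted p = 0.00177), calcium handling and ion channel genes (adjusted p = 0.0036, where 1 of 34 members, Slc8a1, rose) and epicardial markers (adjusted p = 0.0278, with none of 7 passing and 1, Aldh1a1, falling when adjusted over the list alone). Of these, the epicardial call was kept in 1 of the 6 fits without 1 library, that without sham replicate 1, with adjusted p up to 0.554, and the other 2 in all 6.

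**Figure D4:**
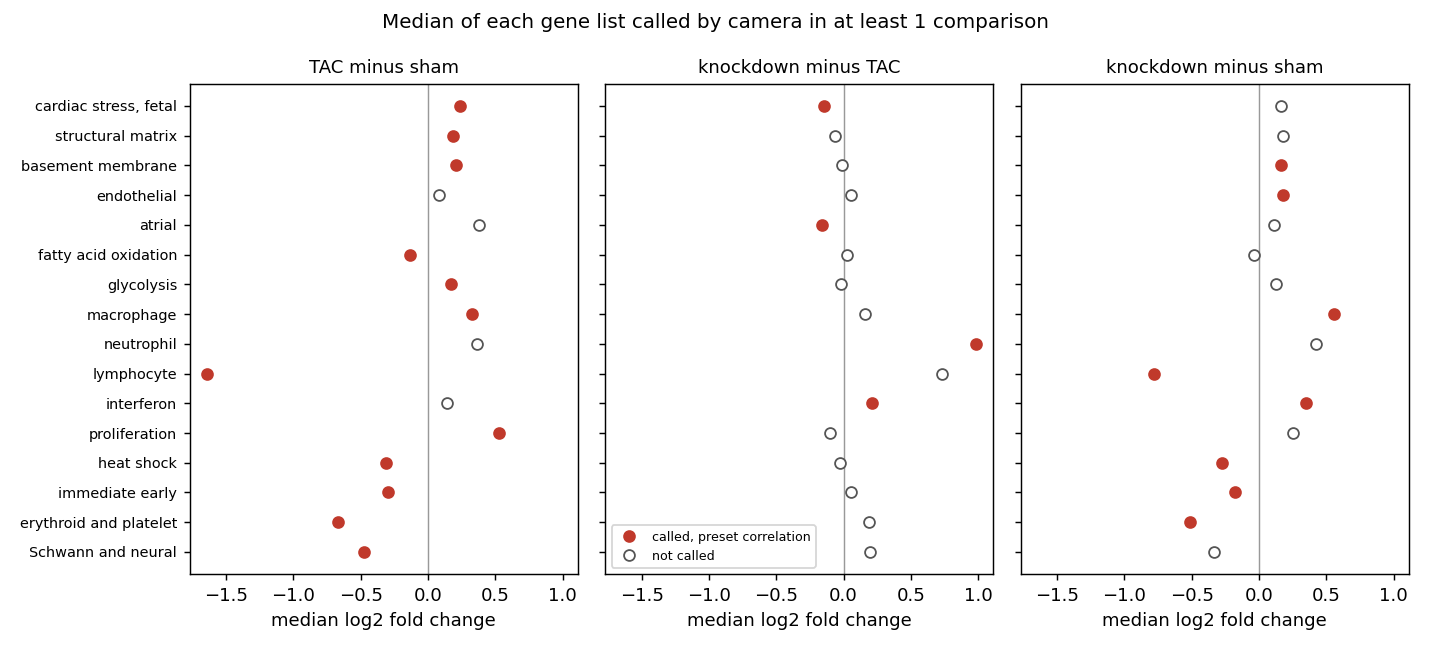
Median log2 fold change (x axis) over the tested members of each gene list that camera called in at least 1 comparison (y axis), for TAC minus sham, knockdown minus TAC and knockdown minus sham. Filled points passed adjusted p below 0.05 with the preset correlation of 0.01. The macrophage list lay at 0.33, 0.16 and 0.56, and the erythroid and platelet list at -0.67, 0.19 and -0.51.

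Knockdown of Snai1 under TAC was compared with TAC alone. Snai1 itself did not pass the test between these groups (log2 -0.51 ± 0.33, limma adjusted p = 0.999). The comparison therefore bears on what Snai1 does in the loaded heart only as far as the knockdown lowered it. The gene nearest to the threshold was Ptgds, which encodes the lipocalin-type prostaglandin D synthase and stood at 497 and 438 CPM with knockdown against 303 and 229 in TAC, a 1.77-fold difference (log2 0.82 ± 0.15, limma adjusted p = 0.797). Nr4a1 stood at 38.7 and 26.2 against 18.2 and 15.2 (log2 0.93 ± 0.20), and Cxcl9, an interferon-induced T cell chemokine gene, at 10.03 and 6.41 against 3.87 and 3.54 (log2 1.11 ± 0.27). Camk2b had a log2 fold change of 0.69 ± 0.19 and the interferon-induced gene Ifi27l2a one of 0.68 ± 0.20. In the other direction the smallest unadjusted p-values were those of Pirt (-0.82 ± 0.20), the ephrin receptor gene Ephb3 (-0.55 ± 0.15), Slc25a53 (-2.54 ± 0.76, with 2 and 10 reads against 23 and 42) and the chromatin remodeller gene Chd6 (-0.37 ± 0.11). None of these genes passed the test. In the alternative with the replicate number as a block, Ptgds alone passed (limma adjusted p = 0.0348), though the replicate numbers are not known to pair the mice. Lck, a T cell kinase gene, had 14 and 13 reads with knockdown, 2 and 0 in TAC, and 13 and 13 in sham.

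No gene was called higher and none lower (0 and 0 by limma, and 0 and 0 by limma-voom and robust limma), and 299 genes had an unadjusted p below 0.05, where chance gives 722. The groups did not overlap for 28.5% of genes, where chance gives 33.3%. In simulated libraries of the same depth and number, where changes were placed between TAC and sham and not between knockdown and TAC, the test recovered 77% of genes changed 2-fold and 90% of those changed 4-fold. The changed genes had a mean of at least 20 reads, and the median standard error was 0.16 there against 0.19 in the data. The simulated spread was taken from genes with a mean of at least 500 reads. Between knockdown and TAC, 4.73% of simulated genes had an unadjusted p below 0.05 by limma, a larger share than in the data. The recovery is therefore not the power of this comparison. In the columns as deposited, 6593 of 19320 genes were called higher and 5544 lower.

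Interferon-stimulated genes were higher as a group with knockdown than in TAC (median 0.21, camera adjusted p = 2.98e-04; adjusted p = 0.995 with an estimated correlation). No member of 37 passed, over all genes or adjusted over the list alone, and Ifit3b had a log2 fold change of 0.84 ± 0.26. Without knockdown replicate 1 the median was 0.05 and the list was not called, and it was 0.39 without knockdown replicate 2, 0.10 without TAC replicate 1 and 0.33 without TAC replicate 2. Atrial genes were lower (median -0.16, adjusted p = 0.0118; adjusted p = 0.995 with an estimated correlation), as were the cardiac stress genes (median -0.15, adjusted p = 0.0211; adjusted p = 0.995 with an estimated correlation). No gene of either list passed in either way. Nppa, a member of both, stood at 106 and 205 CPM against 173 and 346 (log2 -0.73 ± 0.31), and the atrial myosin light chain gene Myl4 had a log2 fold change of -0.52 ± 0.21. The cardiac stress median turned to 0.11 and the call was lost without TAC replicate 2, and the call was also lost with quantile normalization and without knockdown replicate 1 (median -0.04), while the median was -0.46 without TAC replicate 1 and -0.31 without knockdown replicate 2. The atrial list was not called without TAC replicate 1 or knockdown replicate 1 (median -0.08 without the latter). Neutrophil markers were higher (median 0.98, adjusted p = 0.0237; adjusted p = 0.995 with an estimated correlation). None of the 5 passed in either way, the call was lost without TAC replicate 1 or knockdown replicate 1, and the median was -0.24 without the latter and 1.69 without knockdown replicate 2. The macrophage list was not called (median 0.16, adjusted p = 0.0967), nor were lymphocyte markers (median 0.73, camera adjusted p = 0.0948). Structural matrix genes (median -0.06, adjusted p = 0.189) and transcription factors of the mesenchymal transition (median 0.04, adjusted p = 0.906) were not called either. Camera called 4 of 39 lists, 0 held with an estimated correlation, and fry called 0, for 1 direction (smallest adjusted p = 0.997) or for either (smallest adjusted p = 1).

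TAC with Snai1 knockdown was also compared with sham. Of the fixed lists, 3 of 29 macrophage markers rose, and 1 of 10 erythroid and platelet markers, 2 of 24 immediate early genes and 1 of 18 heat shock genes fell. Among single genes, Mpeg1 rose 4.39-fold, Ms4a4a 9.19-fold, Ms4a7 7.30-fold, Clec4n 7.22-fold, Lgals3 5.38-fold and Cd68 3.07-fold. Ccl8 rose 18.0-fold, to 110 and 35 reads from 4 and 2. Hpgds, the prostaglandin D synthase gene of immune cells, rose 4.57-fold, Lilr4b, an inhibitory receptor gene with a close paralog that can share its reads, 3.75-fold, and Ssu2 3.32-fold.

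Ppbp, a member of the erythroid and platelet list, was 8.25-fold lower. F5 (coagulation factor V) was 18.3-fold lower, Tubb1 (the beta-tubulin of platelets) 13.6-fold and Nrgn 6.73-fold, none of which is on a list fixed beforehand. Nr4a3 was 4.61-fold and Nr4a1 2.49-fold lower. Hspa1b, an inducible heat shock gene, was 5.20-fold lower, at 18.9 and 7.67 CPM against 39.3 and 100 in sham. The secreted factor genes Angptl7 and Wif1 were 2.29-fold and 2.16-fold lower, and Bcl6, a transcriptional repressor gene, was 2.27-fold lower.

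In all, 20 genes were higher and 15 lower than in sham (limma, Benjamini-Hochberg adjusted p below 0.05, smallest 0.000525 for Mpeg1 and Nrgn), and 1271 had an unadjusted p below 0.05, where chance gives 722. The groups did not overlap for 39.3% of genes, where chance gives 33.3%, and the columns as deposited gave 7993 higher and 5676 lower. Here too, leaving out 1 library cannot turn the sign of a gene whose groups do not overlap. Without sham replicate 1 the test called 25 higher and 25 lower, without sham replicate 2 it called 3 and 2, without TAC replicate 1 it called 10 and 12, without TAC replicate 2 it called 9 and 12, without knockdown replicate 1 it called 1 and 8, and without knockdown replicate 2 it called 15 and 4. Of the 35 called genes, 2 (Mpeg1 and Nrgn) passed in all 6 of these fits and 7, among them Ssu2 and Wif1, passed in none, and all 35 kept their sign in each.

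The macrophage list was higher than in sham (median 0.56, camera adjusted p = 2.62e-08; adjusted p = 0.903 with an estimated correlation), with 3 of 29 members rising over all genes and, adjusted over the list alone, 17 rising and 2 falling. Interferon-stimulated genes were higher (median 0.35, adjusted p = 1.35e-05; adjusted p = 0.903 with an estimated correlation). None of the 37 passed over all genes and 3 rose when adjusted over the list alone, with Ifi27l2a at 0.89 ± 0.20 and Oasl2 at 0.88 ± 0.22, and the list was not called without knockdown replicate 1 (median 0.15). Basement membrane genes (median 0.17, adjusted p = 0.0335; adjusted p = 0.903 with an estimated correlation) and endothelial markers (median 0.17, adjusted p = 0.0214; adjusted p = 0.903 with an estimated correlation) were higher. No member of either passed over all genes, 3 and 1 rose when adjusted over the list alone, and neither was called without sham replicate 1 or knockdown replicate 1 (medians 0.09 and 0.07 without the latter, and 0.28 for the endothelial list without knockdown replicate 2). Median ratio scaling also ended the calls of the basement membrane list and of the lymphocyte list.

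The lists of heat shock genes (median -0.28, adjusted p = 5.24e-11; adjusted p = 0.524 with an estimated correlation), immediate early genes (median -0.18, adjusted p = 6.27e-09; adjusted p = 0.808 with an estimated correlation) and erythroid and platelet genes (median -0.51, adjusted p = 2.47e-09; adjusted p = 0.262 with an estimated correlation) were lower than in sham. Over all genes 1 of 18, 2 of 24 and 1 of 10 members fell, and 7, 5 and 4 fell when adjusted over the list alone. The erythroid and platelet median was -0.15 without sham replicate 1, -0.85 without sham replicate 2 and -0.21 without knockdown replicate 1, and the immediate early median was -0.33 without sham replicate 1 and -0.35 without knockdown replicate 1. Lymphocyte markers were lower (median -0.78, adjusted p = 0.0128; adjusted p = 0.903 with an estimated correlation), with no member of 12 passing in either way, a median of 0.10 and no call without sham replicate 1, and a median of -2.01 without sham replicate 2, where summed globin genes were 2498 CPM in sham replicate 1 and 1287 in sham replicate 2. Structural matrix genes were not called (median 0.18, adjusted p = 0.091), though Fbn1 rose and Fmod (fibromodulin) and Thbs1 (thrombospondin-1) fell among the 36. Camera called 4 lists higher and 4 lower, 0 held with an estimated correlation, and fry called 0 in its test for 1 direction (smallest adjusted p = 0.178). Its test for members that change in either direction called 3: erythroid and platelet markers (adjusted p = 0.00618), epicardial markers (adjusted p = 0.0423, none of 7 passing over all genes and 1, Aldh1a1, falling when adjusted over the list alone) and Notch and Wnt pathway genes (adjusted p = 0.0423, none of 26 passing over all genes, and Notch3 rising and Dkk3 falling when adjusted over the list alone). Of the 6 fits without 1 library, the erythroid and platelet call was kept in none (adjusted p from 0.0701 to 0.153), the epicardial call only in that without sham replicate 1 (up to 0.833), and the Notch and Wnt call only in those without TAC replicate 1 or 2 (up to 0.857).

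Whether knockdown moved genes altered by TAC back towards sham was examined over the pair of comparisons that share the TAC libraries. No gene was called in both with opposite signs (0 by limma, since none was called in the second, where 299 had an unadjusted p below 0.05). Across the 14447 genes, which are not independent replicates, the correlation of the log2 fold changes was -0.43, where unchanged groups sharing the same TAC libraries gave -0.50 ± 0.02 (SD, 100 draws). The covariance was -0.0774 against -0.0756 ± 0.00378 in the draws. With a different TAC library in each comparison, the correlation was 0.04, against 0.000718 ± 0.0203 in draws of that form. The covariance was then 0.0102 against 0.000149 ± 0.00462, and 48.5% of genes had opposite signs against 49.9 ± 0.367%. None of these values lay on the side of a reversal. With the TAC libraries shared, opposite signs were found for 63.4% of genes, against 66.6% in the draws. The draws hold no TAC effect, and such an effect weakens the correlation of -0.43 and lowers the share of 63.4%. Neither value can therefore show whether reversal went beyond what the shared libraries give. The covariance of -0.0774, which a TAC effect alone would leave unchanged, was near that of the draws. Of the 23 genes called after TAC, 17 (73.9%) had the opposite sign with knockdown, 7 of the 12 higher and 10 of the 11 lower. Calling genes on the TAC libraries that both comparisons share favours opposite signs. Draws in which these genes kept their fitted TAC effect and knockdown changed nothing, run after this count was seen, gave 57.9 ± 10.5% (SD), and 6 of 100 reached 73.9%. In these draws, as in those above, each gene varied independently. Genes that vary together would widen the spread of the draws, so the SDs given are too narrow. The fitted effects belong to genes picked for passing and are thus likely too large. Smaller effects would give more opposite signs in the draws, so 73.9% may be less unusual than 6 of 100.

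The comparisons of TAC and of knockdown with sham shared 9 of their higher genes and 4 of their lower ones, and this overlap was not set against a value for unchanged groups that share the sham libraries. The correlation of their log2 fold changes across genes was 0.69, against 0.50 ± 0.02 in unchanged groups sharing the sham libraries, and the covariance was 0.154 against 0.076 ± 0.00406. Here too genes were drawn independently, so these SDs are too narrow where genes vary together. With a different sham library in each comparison the correlation was 0.19 and the covariance 0.0609. Part of the overlap of called genes may come from the shared sham libraries, since with 2 of them no separate sham group with replicates can be formed for each comparison.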

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

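Limma-voom, the columns as deposited and the either-direction test of fry were tests chosen after the data were seen. The counts for TAC against sham, 12 higher and 11 lower, became 20 and 22 with a pseudocount of 1 CPM, 5 and 4 without a filter, 6 and 4 without the low-level genes of a stricter filter, and 0 and 2 (Gp5 and Sall3) by limma without the trend. A pseudocount of 5 CPM gave 7 higher, limma-voom 7 higher, median ratio scaling 17 lower, and a minimum log2 fold change of 1 gave 7 lower. For knockdown against sham, 20 higher and 15 lower, they became 7 and 7 without a filter, 4 and 4 with that filter, and 0 and 1 by limma without the trend, while 13 were higher with quantile normalization, 6 by limma-voom, 9 when only the 2 groups were fitted and 12 with the minimum log2 fold change of 1. Leaving out 1 library gave 1 to 27 higher and 3 to 24 lower in TAC, and 1 to 25 higher and 2 to 25 lower with knockdown, against sham, where a lone sample is assumed to vary like the other groups.

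For knockdown against TAC limma called 0 genes under each of these alternatives (299 at an unadjusted p below 0.05, 298 by limma-voom). With the replicate number as a block, TAC against sham gave 20 higher and 20 lower and knockdown against TAC gave 1 higher, Ptgds (limma adjusted p = 0.0348). The data do not pair equal replicate numbers. The log2 differences between replicates 1 and 2 correlated at -0.22 for sham and TAC, 0.13 for sham and knockdown and -0.13 for TAC and knockdown. By these signs sham replicate 1, TAC replicate 2 and knockdown replicate 1 fall on the same side, as on the second principal component. A block of that form was not tried. The columns as deposited gave 7638 higher and 6174 lower, 6593 and 5544, and 7993 and 5676 in the 3 comparisons, 6561 opposite changes where the resolved libraries gave 0, and a correlation of -0.46. The same test on simulated unchanged genes in that form called 64.2% in TAC against sham, so mixed columns alone can give counts of this size.

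Snai1 had a log2 fold change from -0.66 to -0.35 between knockdown and TAC, from -0.74 to -0.17 between knockdown and sham and from -0.23 to 0.34 between TAC and sham when 1 library was left out, the last turning negative without sham replicate 2 and, at -0.024, with quantile normalization. It passed in the columns as deposited alone, at -0.51 and -0.47 against TAC and sham. The gene lists called numbered 12, 4 and 8, and 0, 0 and 0 with an estimated correlation, by fry for 1 direction, and in the deposited columns with an estimated correlation, with 3, 0 and 3 by fry for members changing in either direction, while leaving out 1 library gave 8 to 17, 4 to 13 and 8 to 12. The correlation of -0.43 between TAC and knockdown changes turned to 0.035 without a shared TAC library. Of 1056 values of single named genes other than Snai1 under alternatives, 808 stayed on the same side of the threshold, 227 lost the call, 21 gained it and 0 turned sign. The 1056 values include named genes of knockdown against TAC that had not passed, for which staying uncalled counts as the same side. All 227 lost calls were of genes called against sham. Of the 20 named genes called in TAC against sham, 19 kept the call with quantile normalization, 12 by limma-voom and 0 without the trend. For knockdown against sham, 18, 11 and 0 of 20 did. For named genes whose groups do not overlap, leaving out 1 library could not turn a sign. Causes of the shifts under alternatives were not tested, apart from the mixing. Count tests were not run, as the plan followed the log scale of the deposited file, though the resolved whole counts would have allowed them. Low depth limits Snai1, with 50 to 81 reads per library.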

Other observations

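The platelet and globin test and both tests of the column structure were chosen after the results were seen, and the tests on macrophage markers before. Among calcium handling and ion channel genes, Slc8a1, the sodium and calcium exchanger gene of heart muscle, rose in TAC against sham (log2 fold change 0.65 ± 0.11, limma adjusted p = 0.0349, higher in both TAC libraries than in both sham libraries). It was the only 1 of 34 members to pass over all genes, and 4 rose and 1 fell when adjusted over the list alone. The potassium channel gene Kcnk3 had a log2 fold change of 0.48 ± 0.10 and the calsequestrin gene Casq2 one of 0.44 ± 0.11, and the list was not called (median 0.02, camera adjusted p = 0.406). Ednra, an endothelin receptor gene, rose in TAC (0.69 ± 0.12) and with knockdown (0.62 ± 0.12) against sham. Ednra passed in 0 of the 6 fits without 1 library in either comparison, and Slc8a1 in 3. With knockdown against sham, 4 genes picked after their values were seen and held by no list, Apoe (apolipoprotein E, 0.90 ± 0.17), C3ar1 (a complement receptor, 1.30 ± 0.23), C4b (complement component 4, 0.84 ± 0.16) and Stab1 (a scavenger receptor, 0.71 ± 0.13), rose. Of these, C3ar1 and Stab1 passed in 0 of the 6 fits without 1 library, and Apoe and C4b in 1. In TAC against sham, where they did not pass, the log2 fold changes of Apoe, C3ar1, C4b and Stab1 were 0.73, 0.93, 0.60 and 0.57, and knockdown against TAC gave an adjusted p of 0.999 for each. Cardiomyocyte genes had a median of 0.05 in TAC against sham (adjusted p = 0.369).

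Pdk4, a kinase gene that restrains pyruvate oxidation, had 70.7 and 327 CPM in the 2 sham libraries. The male-linked gene Ddx3y had between 1046 and 1711 reads per library, while Xist, expressed from the inactive X chromosome, had 45 in TAC replicate 2 and between 1 and 10 in the other 5 libraries. The first 2 principal components held 28.6% and 21.8% of the variance, and the second set the 2 libraries of each group apart, at 34.1 and -27.0 in sham, -22.1 and 7.53 in TAC and 18.7 and -11.3 with knockdown. The gene with most reads was the predicted gene Gm10925 in sham replicate 1 (5.21% of reads) and knockdown replicate 1 (4.19%), and Myh6, the main myosin heavy chain gene of the mouse ventricle, in the other 4 libraries.

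The 2 deposited columns of a group differed by less than the sampling of reads would give (chi-square per gene at most 0.58). A single library sequenced as 2 independent sets of reads is argued against, since each column would then hold whole reads, and at most 25.03% of the values in a column were whole once the log was undone. A mixture of 2 sets of counts in shares of 60% and 40% is a candidate explanation, as it made 99.9% of resolved values whole. Why the columns take this form stays open, since no source used here describes it. No biological explanation was tested.

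Macrophage markers were higher in TAC than in sham as a list, with 2 of 29 passing over all genes (camera adjusted p = 2.45e-05; adjusted p = 0.887 with an estimated correlation). That 1 library decides this is argued against, as the lowest median without 1 sham or TAC library was 0.26 (without TAC replicate 2). A lower share of heart muscle RNA in TAC may also raise these markers, and it would raise those of other cell types alike. It would also lower cardiomyocyte genes, which had a median of 0.05 with 20 of 30 positive and 10 negative. That list was not called (camera adjusted p = 0.369). The macrophage median exceeded that of lymphocytes by 3.58 standard errors, but that of endothelial cells by 1.26, of pericytes and smooth muscle by 1.30 and of resting fibroblasts by 0.87, so the explanations cannot be told apart for these lists, whose spread between genes is wide. These standard errors are over the listed genes, taken as independent, and do not measure the spread between libraries. The lymphocyte median of -1.64 was -0.32 without sham replicate 1. More macrophages, or more macrophage RNA per cell, after pressure load stays among the open explanations, untested.

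Platelet genes were lower in TAC than in sham: 16 tested genes had a median log2 fold change of -2.69, all 16 were negative and 3 fell over all genes, but Ppbp, Nrgn, Itga2b, F5 and Tubb1 were on this list because their values had been seen. More blood left in the sham hearts may contribute, since all 4 globin genes were also negative (from -0.67 to -0.46), with a median of -0.57, higher by 2.12 than that of the platelet genes. Without those 5 genes, 11 platelet genes had a median of -1.64, all negative with none passing, and the difference from globin was 1.84 standard errors over the listed genes, so this explanation stays open. Summed platelet genes had 92.0 and 135 CPM in sham, 28.7 and 27.6 in TAC and 33.7 and 28.3 with knockdown, and globin genes 2498 and 1287, 1258 and 1142, and 1098 and 1599. The high globin sum was thus that of sham replicate 1. Sham replicate 2 had the highest platelet sum, while its globin sum lay below that of knockdown replicate 2. For sham replicate 2 the globin sum therefore gave no sign of more blood, an observation on a single library. Clotting or handling of the tissue, and a biological effect of TAC, were not tested.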
